A study of Ovis aries with 8 samples.

How the data were processed

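RNA was measured in hand-picked pancreatic islets of 8 near-term sheep fetuses, 4 infused with norepinephrine and 4 with the diluent, per the labels' protocols. The labels give each fetus its own weight, age and number, so the replicates are separate animals. Messenger RNA was selected and libraries were built with a TruSeq RNA kit for paired reads of 100 bp, per the labels' protocols. Whether the kit marked strand is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. TopHat2 2.0.1, Cufflinks 2.1.1, Cuffdiff and the sheep genome build Oar_v3.1 are named in the submitters' processing notes, with no version for Cuffdiff. Filters and the annotation used are not given in the sources used here.

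The deposited table holds 25000 rows with a gene name, a locus and 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each of the 8 animals, per the file headers. It holds no counts. No other sample column was present (0 columns left out). Summed FPKM ran from 768021 to 1112624 per animal. Depth is known only in relative terms: in short genes with few fragments the FPKM of an animal moves in steps of 1 fragment. Against control 1, those steps gave a relative depth of 1.17 for control 3, 1.08 for control 4, 1.01 for norepinephrine 2, 0.650 for norepinephrine 1 and 0.726 for norepinephrine 3. Control 2 and norepinephrine 4 shared no such step with control 1 (at most 4 genes at any 1 ratio), and their depth is unknown. No counting interval was therefore computed.

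Columns were matched to animals by the number in the column name and in the sample label. Of the rows, 6805 carry only an Ensembl sheep identifier, 165 merge several names, and 13316 match a symbol in the NCBI RefSeq gene table of another assembly (ARS-UI_Ramb_v3.0), which was used for names only. Coordinates are those of the file on Oar_v3.1, with the start raised by 1 to count from 1. A list member was the row with exactly its symbol. Of duplicate rows the one with the highest mean was used, and merged rows were not assigned to either gene.

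Values were analysed as log2(FPKM + 1), a scale that understates the change of low genes. Rows with a mean FPKM of at least 1 over the 8 animals were tested (13252 genes). Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed before the data were examined (29 lists, 28 with at least 5 tested genes) were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01. They were also tested by camera with an estimated correlation, by fry, which asks whether members move on balance one way, and by an exact two-sided permutation test of the mean log2(FPKM + 1) per animal. For 4 against 4 animals the smallest p of such a test is 0.0286. Fetal weight and gestational age were compared by the same exact test.

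The rule for named genes, also fixed before the data were examined, took the 10 largest rises and 10 largest falls past the threshold with no overlap between groups (0 genes here), 26 genes of islet function and adrenergic signalling whatever their outcome, and from each list the 3 members past the threshold with the largest change or, where it had none, the 2 members with the highest mean FPKM. Genes named outside this rule are said to be chosen after their values were seen. Some genes taken by the rule are not reported here.

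The animal numbers in the labels start with 09 or 10. The labels do not say what this means. The 4 animals numbered 09 are 1 control and 3 norepinephrine animals, and the 4 numbered 10 are 3 controls and 1 norepinephrine animal. The mean difference of each list within each number group is given beside the pooled value. Values of single genes within the number groups, and values from a model with the prefix as a covariate, are given for some genes and lists only. A lone animal in such a fit is assumed to vary like the others. Replicate numbers of the 2 groups belong to different animals and did not pair them, so no block entered the main model.

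The gene-level test was tested on simulated values with the means and spreads of the 13252 genes, in which 100 genes were changed by 2-fold and 100 by 4-fold (10 simulations). The changed genes were drawn only from genes well above the abundance filter. Among these the test recovered 68.1% of the 2-fold and 97.0% of the 4-fold changes, with 8.0 false calls on average. Recovery of changes in genes near the filter, such as MKI67, was not simulated and is unknown. With the spread between animal numbers left in the simulated values, 61.7% and 95.0% were recovered. The list test with the preset correlation found a cell-cycle list lowered by 0.5 in 10 of 10 simulations with independent genes, and called 0 of 270 unchanged lists. Members of the real lists were not independent. Their estimated correlation was 0.35 for cell cycle, 0.57 for acinar markers, 0.66 for oxidative phosphorylation and 0.75 for ribosomal proteins. The simulation therefore does not measure false calls in such lists.

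Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, equal totals without the hormone rows, limma without the trend, covariates for sex, number prefix, gestational age or acinar markers, a replicate block, an estimated inter-gene correlation and leaving out each animal. Fits within each number group, and the prefix together with median-of-ratios scaling, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.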

Results

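The series compared pancreatic islets of near-term Columbia-Rambouillet singleton sheep fetuses after 7 days of intravenous norepinephrine with islets of fetuses given the diluent. It asks how a sustained rise in this catecholamine, which acutely restrains insulin secretion through alpha-2 adrenergic receptors, leaves the islet transcriptome. The infusion ran at 1 µg/min on day 1, at 2 µg/min on days 2 to 4 and at 4 µg/min on days 5 to 7. Controls received the diluent alone, saline with ascorbic acid. Each group held 4 fetuses, and RNA abundance was measured by sequencing as FPKM. All ± values are SDs over n = 4 animals unless an SE is named, and fold changes are log2 differences of FPKM + 1, norepinephrine minus control.

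Fetuses given norepinephrine weighed 3.125 ± 0.403 kg and controls 4.20 ± 0.589 kg, a difference of -1.075 kg that missed the threshold (exact permutation test, two-sided p = 0.0571). Gestational age was 138.25 ± 0.957 days with norepinephrine and 139.75 ± 0.5 days in controls (exact permutation p = 0.0857). The weight difference was -0.667 kg among animals numbered 09 and -0.7 kg among those numbered 10. The female fetuses were control 2 and norepinephrine 3.

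Libraries parted by the first 2 digits of the animal number more than by treatment. Summed FPKM lay between 981583 and 1112624 in the 4 animals numbered 09 and between 768021 and 796149 in the 4 numbered 10. The first principal component, with 28.9% of the variance, put all 09 animals on 1 side and all 10 animals on the other. Correlations of log2 values ran from 0.939 to 0.966 within controls, from 0.922 to 0.950 within the norepinephrine group and from 0.925 to 0.963 between groups. With treatment in the model, 2187 genes differed between the number groups by limma at an adjusted p under 0.05, 803 higher and 1384 lower in 10. As lists, transcripts of ribosomal proteins (median -0.88, camera adjusted p = 1.17e-09), oxidative phosphorylation (median -0.60, adjusted p = 3.90e-08) and acinar cells (median -1.46, adjusted p = 0.0283) were lower in animals numbered 10. Glycolysis and hypoxia (median -0.59, adjusted p = 0.00162), antioxidant defence (-0.41, 0.0236), the unfolded protein response (-0.36, 0.0317) and immediate-early genes (-0.46, 0.0445) were lower there too, and G-protein and cAMP signalling was higher (0.19, 0.0317). All these list calls used camera with the preset correlation of 0.01, and no other list test was run between the number groups. In the comparison of treatment groups the estimated correlation was 0.75 for ribosomal proteins, 0.66 for oxidative phosphorylation and 0.57 for acinar markers. Because 3 of the 4 norepinephrine animals are numbered 09 and 3 of the 4 controls 10, differences between the number groups enter the treatment comparison in part.

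**Figure D1:**
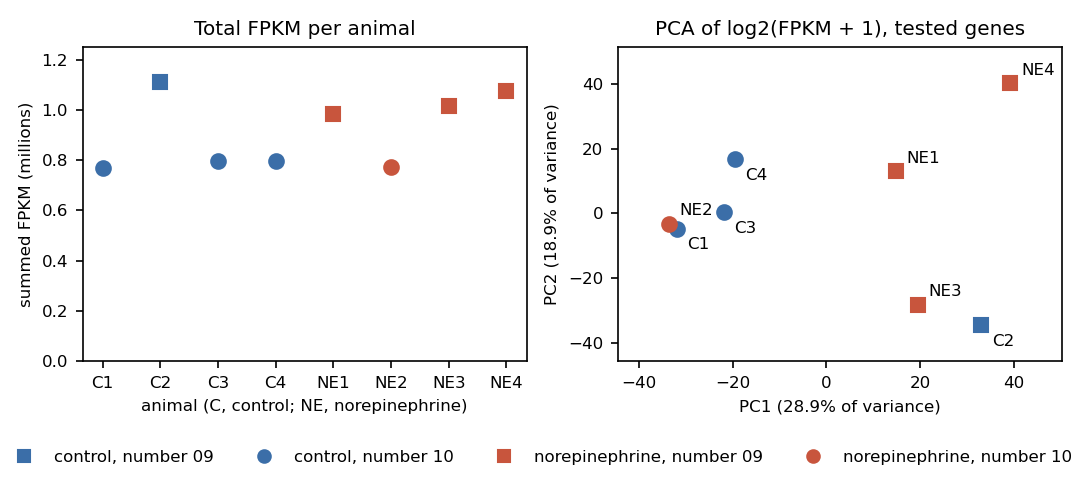
Left, summed FPKM for each animal. Right, the first 2 principal components of log2(FPKM + 1) over 13252 genes, with 28.9% and 18.9% of the variance. Colour marks the group (C, control; NE, norepinephrine) and shape the number prefix. Animals numbered 09 lie at 981583 or above in total and to the right on the first component.

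The main comparison asked which islet transcripts differed after norepinephrine. No single gene passed: limma gave 0 of 13252 genes at an adjusted p under 0.05, 0 higher and 0 lower, and the lowest adjusted p was 0.210. At an unadjusted p under 0.05 there were 975 genes (479 higher, 496 lower), where chance alone gives 662.6. Leaving out 1 animal at a time, this count ran from 588 (without control 3) to 2185 (without control 2). Without the variance trend there were 957, and again 0 after adjustment. The 2 groups did not overlap in 560 genes (4.23%), where chance gives 2.86%. With the number prefix as a covariate, 1552 genes had an unadjusted p under 0.05 and 1 passed after adjustment. That gene, chosen after its values were seen, was NNAT (neuronatin, chromosome 13, 66032357 to 66033952), an imprinted transcript known in beta cells. It stood at 160.2 ± 40.3 FPKM with norepinephrine and 43.2 ± 16.9 in controls, a log2 difference of 1.90 (SE 0.268, limma adjusted p = 0.210) and of 1.48 with the prefix in the model (adjusted p = 0.0475). The difference was 1.36 among animals numbered 09 and 1.60 among those numbered 10.

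Of the 28 gene lists with enough members, 7 stood apart from the other genes by camera with the preset correlation. Islet hormones, unfolded protein response, acinar markers, oxidative phosphorylation and ribosomal proteins were higher with norepinephrine, and cell cycle and mitosis, and antigen presentation and interferon response, were lower. With an estimated correlation 0 of the 28 lists were called (lowest adjusted p = 0.579), and 0 were called by fry (lowest adjusted p = 0.229) or by the exact permutation test (lowest adjusted p = 0.600). With the prefix as a covariate 9 lists were called, and 0 with the prefix and an estimated correlation (lowest adjusted p = 0.638).

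**Figure D2:**
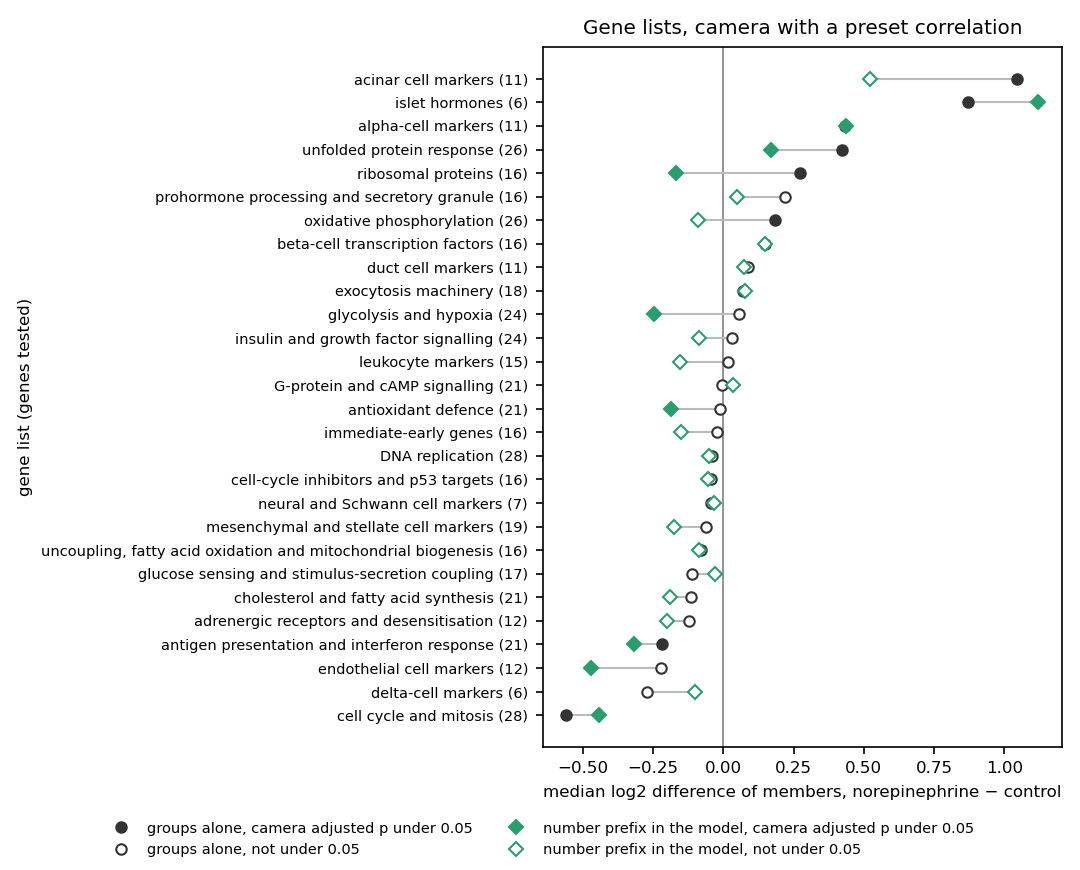
Median log2 difference (norepinephrine minus control) of the tested members of each gene list, for the comparison of groups alone (circles) and with the number prefix in the model (diamonds). Filled symbols have a camera adjusted p under 0.05 with the preset correlation. Cell cycle and mitosis lies at -0.56 and -0.44, while ribosomal proteins go from 0.27 to -0.17.

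Transcripts of cell division were lower after norepinephrine. Of 28 tested cell-cycle and mitosis genes, 24 had lower means, with a median log2 difference of -0.56 (camera adjusted p = 2.90e-12). With an estimated correlation, which was 0.35 for this list, camera did not call it (adjusted p = 0.579). The number of members lower was 0 over all genes tested and 11 adjusted over the list alone. These 11 were named after their values were seen, and no test of a cell-cycle phase was made. UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 14.6 ± 4.68 to 4.98 ± 2.43 FPKM. TOP2A, the topoisomerase of dividing cells, fell from 5.88 ± 1.46 to 2.39 ± 0.649, although the file lists it at the same locus as RARA, so its value is uncertain. KIF20A, a kinesin of cytokinesis (chromosome 5, 46994290 to 47001867), fell from 3.85 ± 0.406 to 1.43 ± 0.435. MKI67, which encodes the proliferation antigen Ki-67 (chromosome 22, 46439179 to 46468099), fell from 1.70 ± 0.233 to 0.684 ± 0.153. PRC1, AURKB, CDC20, CCNA2, CCNB2, CDC25B and BUB1B were the other members, and their limma adjusted p over the list alone lay between 0.00837 and 0.0356.

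The most abundant members of this list followed no single course. CDK4 stood at 58.5 ± 8.92 FPKM with norepinephrine and 52.2 ± 2.56 in controls, and the difference turned negative with equal library totals. CCND3 stood at 26.1 ± 7.97 and 39.2 ± 7.36. CCND2, a cyclin of beta-cell replication, was at 32.2 ± 7.88 and 28.2 ± 5.53 and did not pass (log2 0.17, SE 0.20). Within the number groups the mean cell-cycle difference was -0.42 among animals numbered 09 and -0.50 among those numbered 10, and with the prefix in the model the list median was -0.44 (adjusted p = 1.51e-07; adjusted p = 0.638 with an estimated correlation), with 11 members lower adjusted over the list alone, CCND3 in place of BUB1B. The mean over the list gave the smallest p that the exact permutation test allows (0.0286), which did not pass over the 28 lists (adjusted p = 0.600). Leaving out control 1, which had the highest list mean, reduced the 11 members to 6. With a mean FPKM of at least 5, 14 members were tested, with a median of -0.43 (camera adjusted p = 0.00202), and 2 were lower adjusted over the list alone. Acinar markers were higher in the same comparison (median 1.04), and norepinephrine 3 had the highest acinar mean (5.79) and the lowest cell-cycle mean (2.09). With the acinar mean as a covariate the cell-cycle median was -0.40 (adjusted p = 1.71e-06), with 10 members lower adjusted over the list alone.

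DNA replication genes were not called: the median over 28 genes was -0.040 (adjusted p = 0.577), with a mean difference of 0.0047 in 09 and -0.18 in 10. The list was called lower with gestational age as a covariate (median -0.20, adjusted p = 0.0107) and without norepinephrine 4 (median -0.096, adjusted p = 0.0193), against an adjusted p = 0.860 with an estimated correlation in the comparison of groups alone. Among its members were PCNA at 92.5 ± 10.4 and 100.5 ± 11.7 FPKM and MCM7 at 86.8 ± 16.3 and 86.2 ± 5.60, norepinephrine before control. Cell-cycle inhibitors and p53 targets had a median of -0.043 (16 genes, adjusted p = 0.741), with CDKN1A, the inhibitor p21, at 349.6 ± 137.8 and 393.6 ± 63.6 and BTG1 at 922.4 ± 289.5 and 1133 ± 377.1. Their mean difference was -0.18 in 09 and -0.047 in 10.

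**Figure D3:**
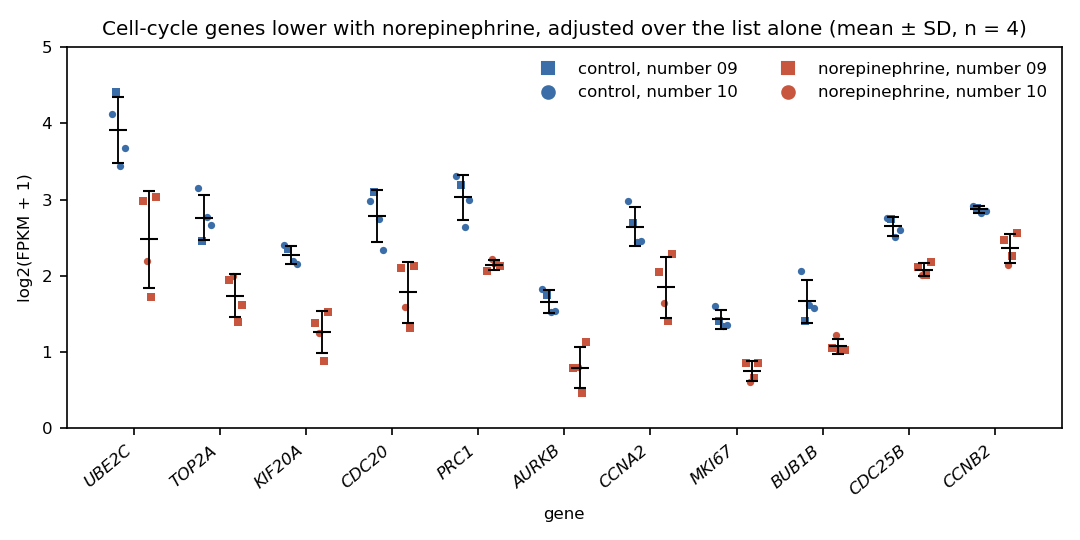
log2(FPKM + 1) of the 11 cell-cycle genes that were lower adjusted over the list alone, for each animal, with the mean and SD of each group (n = 4). Colour marks the group and shape the number prefix. MKI67 lies at 1.70 FPKM in controls and 0.684 FPKM with norepinephrine, and UBE2C at 14.6 and 4.98.

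Islet hormone transcripts were higher as a list, and no member passed on its own, over all genes or adjusted over the list alone (0 of 6). The median log2 difference of the 6 tested hormones was 0.87 (camera adjusted p = 0.00869), and 0.579 was the adjusted p with an estimated correlation. SST, which encodes somatostatin (chromosome 1, 197885693 to 197888971), stood at 1142 ± 717.4 FPKM with norepinephrine and 392.7 ± 368.7 in controls (log2 1.73, SE 0.67, limma adjusted p = 0.628), with differences of 2.05 in 09 and 2.33 in 10. GCG, the glucagon gene, stood at 2073 ± 1497 and 1348 ± 752.9, and UCN3, which encodes urocortin 3, at 933.9 ± 246.5 and 627.7 ± 184.5. All 6 were higher within both number groups, with a mean difference of 1.07 in 09 and 1.15 in 10, and a median of 1.12 with the prefix in the model (adjusted p = 0.0112; adjusted p = 0.638 with an estimated correlation). The call was lost without control 2 (adjusted p = 0.121) or norepinephrine 2 (adjusted p = 0.0819), and with gestational age as a covariate (median 0.50, adjusted p = 0.0651). INS, PPY, KCNJ11, ADRA2B and ADRA2C are not listed under these symbols, and MAFA and INSR appear only in merged rows, so none of them was analysed here. IAPP is listed at 0 in all 8 animals; RPL3, a ribosomal gene every cell uses, is also listed at 0, so this can be a failed estimate.

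The 3 lists of islet identity genes were not called in the comparison of groups alone. Alpha-cell markers had a median of 0.43 (11 genes, adjusted p = 0.202), led in abundance by GCG and TM4SF4 (503.4 ± 204.4 and 357.6 ± 93.3 FPKM), and were called with the prefix in the model (median 0.44, adjusted p = 0.0398; adjusted p = 0.638 with an estimated correlation). With the prefix, SLC7A2, an amino acid transporter named after its values were seen, was higher adjusted over the list alone (log2 1.01, limma adjusted p = 0.0310). The mean alpha-cell difference was 0.26 in 09 and 0.63 in 10. Delta-cell markers had a median of -0.27 and a mean of -0.0025 (6 genes, adjusted p = 0.514): SST was higher and RBP4 was at 4827 ± 1752 against 6283 ± 2150. Their mean difference was -0.38 in 09 and 0.53 in 10. Beta-cell transcription factors had a median of 0.15 (16 genes, adjusted p = 0.514), with a mean of 0.038 in 09 and 0.17 in 10, and were called with gestational age as a covariate (median 0.23, adjusted p = 0.0494; adjusted p = 0.807 with an estimated correlation in the comparison of groups alone). PDX1 stood at 272.4 ± 47.6 and 256.9 ± 30.9 FPKM, a difference that turned negative with equal library totals, NKX6-1 at 114.9 ± 36.8 and 95.4 ± 9.35, and PAX6 at 119.9 ± 31.2 and 102.4 ± 17.7.

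Genes of glucose sensing and stimulus-secretion coupling had a median of -0.11 and a mean of -0.019 (17 genes, adjusted p = 0.642). SLC2A2, the glucose transporter GLUT2, stood at 76.8 ± 46.3 FPKM with norepinephrine and 92.3 ± 32.0 in controls, ABCC8, the sulfonylurea receptor subunit of the potassium channel, at 113.9 ± 34.0 and 98.9 ± 38.3, and GLP1R at 4.67 ± 2.34 and 4.07 ± 4.28. The mean difference of the list was -0.19 in 09 and 0.32 in 10, while SLC2A2 differed by 0.19 and 0.22 there and by -0.40 in the pooled groups. Prohormone processing and secretory granule genes had a median of 0.22 (16 genes, adjusted p = 0.202), with CHGA at 4853 ± 829.7 and 3891 ± 1555 and SCG5 at 3829 ± 653.4 and 3235 ± 1167. Their mean difference was -0.045 in 09 and 0.34 in 10. Exocytosis machinery as a whole had a median of 0.069 (18 genes, adjusted p = 0.617), with CPLX2 at 188.5 ± 38.4 and 220.0 ± 40.1 and NAPA at 201.2 ± 20.5 and 173.9 ± 43.4, and a mean difference of 0.020 in 09 and 0.22 in 10. Camera called this list higher with gestational age as a covariate (median 0.16, adjusted p = 0.00423), against an adjusted p = 0.860 with an estimated correlation in the comparison of groups alone. Over all genes 0 members passed, and 2 were higher adjusted over the list alone, both named after their values were seen. SYT13, an atypical synaptotagmin, rose from 134.9 ± 8.56 to 201.8 ± 24.0 FPKM, and RPH3AL, a Rab effector of granule exocytosis also called Noc2, from 44.0 ± 4.02 to 61.0 ± 7.54 (limma adjusted p over the list alone 0.0219 and 0.0493). With the prefix in the model SYT13 alone passed over the list (adjusted p = 0.0258).

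Adrenergic receptors, the direct targets of the infusion, formed a list with desensitisation genes that had a median of -0.12 (12 genes, adjusted p = 0.419). ADRA2A, the alpha-2A receptor (chromosome 22, 30516666 to 30517993), was the most abundant of the receptors in the rule, at 48.2 ± 14.6 FPKM with norepinephrine and 56.6 ± 13.2 in controls, and did not pass (log2 -0.25, SE 0.24, limma adjusted p = 0.809). Its difference was -0.69 among animals numbered 09 and 0.064 among those numbered 10. ADRA1A stood at 4.76 ± 1.09 and 4.71 ± 1.40 and ADRA1B at 1.35 ± 1.04 and 1.21 ± 0.603, and the sign of both turned with equal library totals. ADRB1 at 0.0854 ± 0.0783 and 0.112 ± 0.103 was below the abundance filter. RGS2, a regulator of G-protein signalling, stood at 366.5 ± 86.0 and 442.0 ± 91.2, and RGS16 at 109.5 ± 21.3 and 117.5 ± 7.90. With the prefix in the model, 0 adrenergic members passed over all genes and 1, RGS2, was lower adjusted over the list alone (log2 -0.57, limma adjusted p = 0.0294). The mean difference of the list was -0.22 in 09 and -0.17 in 10.

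G-protein and cAMP signalling had a median of -0.0063 (21 genes, adjusted p = 0.741), with GNAS at 2842 ± 692.3 and 1896 ± 535.8 and PRKAR1A at 621.4 ± 69.2 and 542.5 ± 98.7, and a mean difference of 0.095 in 09 and 0.078 in 10. Immediate-early genes had a median of -0.023 and a mean of 0.033 (16 genes, adjusted p = 0.969), with JUNB at 200.1 ± 42.3 and 180.7 ± 46.7 and IER3 at 206.9 ± 58.5 and 173.5 ± 55.0. Their mean difference was -0.10 in 09 and -0.22 in 10.

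Genes of the unfolded protein response, which includes chaperones of the secretory pathway, were higher as a list: 21 of 26 had higher means, with a median of 0.42 (camera adjusted p = 4.59e-05) and an adjusted p of 0.801 with an estimated correlation. No member passed over all genes or adjusted over the list alone (0 of 26). HSP90B1, the chaperone GRP94, stood at 1304 ± 304.1 FPKM with norepinephrine and 849.9 ± 199.6 in controls, and CALR, calreticulin, at 1379 ± 229.3 and 1002 ± 127.8. The mean difference was 0.016 among animals numbered 09 and 0.27 among those numbered 10, and with the prefix in the model the median was 0.17 (adjusted p = 0.0109; adjusted p = 0.638 with an estimated correlation). The list also differed between the number groups with treatment in the model, by camera with the preset correlation only (median -0.36 in 10 against 09, adjusted p = 0.0317). Acinar markers were higher in the same comparison (median 1.04). With their mean as a covariate the median of the unfolded protein response was 0.20 (adjusted p = 0.0342), and with gestational age 0.10 (adjusted p = 0.0310).

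Oxidative phosphorylation and ribosomal protein genes were higher as lists in the pooled comparison, and their medians were negative with the number prefix in the model. Oxidative phosphorylation had a median of 0.18 (26 genes, adjusted p = 0.0175; 0.807 with an estimated correlation) and -0.090 with the prefix in the model (adjusted p = 0.176), with COX4I1 at 1252 ± 310.1 and 1035 ± 290.3 FPKM and COX5B at 793.5 ± 180.0 and 744.4 ± 330.4. Ribosomal proteins had a median of 0.27 (16 genes, adjusted p = 0.0187; 0.807 with an estimated correlation) and -0.17 with the prefix (adjusted p = 0.0227; adjusted p = 0.638 with an estimated correlation), with RPL19 at 6361 ± 1431 and 5911 ± 2072. COX5B and RPL19 turned negative with equal library totals, and processed pseudogenes can share reads with ribosomal genes. The mean differences were -0.26 and 0.040 for oxidative phosphorylation, and -0.010 and -0.15 for ribosomal proteins, in 09 and 10. With the acinar mean as a covariate the medians were -0.038 and -0.12. In the main direction oxidative phosphorylation was called in 12 of 23 alternatives and ribosomal proteins in 10.

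Other metabolic lists were not called in the comparison of groups alone. Uncoupling, fatty acid oxidation and mitochondrial biogenesis had a median of -0.079 (16 genes, adjusted p = 0.514), with UCP2, a mitochondrial carrier of islets, at 137.5 ± 29.0 and 179.5 ± 55.2 FPKM (log2 -0.36, SE 0.23, limma adjusted p = 0.752) and HADHB at 176.7 ± 42.1 and 233.9 ± 42.2. UCP2 differed by -1.003 in 09 and 0.083 in 10, and the list mean by -0.28 and 0.033. Glycolysis and hypoxia had a median of 0.056 (24 genes, adjusted p = 0.756) and of -0.25 with the prefix in the model (adjusted p = 0.0213; adjusted p = 0.638 with an estimated correlation), with GAPDH at 1937 ± 413.8 and 1714 ± 669.0 and PKM at 470.2 ± 84.6 and 455.9 ± 102.1, and a mean difference of -0.40 in 09 and -0.13 in 10. Antioxidant defence had a median of -0.011 (21 genes, adjusted p = 0.756) and of -0.19 with the prefix (adjusted p = 0.0190; adjusted p = 0.638 with an estimated correlation), with TXN at 1284 ± 157.1 and 1260 ± 250.0 and GPX3 at 964.4 ± 49.7 and 1117 ± 298.5, and a mean difference of -0.34 in 09 and -0.15 in 10. PKM and TXN turned negative with equal library totals. Cholesterol and fatty acid synthesis had a median of -0.12 (21 genes, adjusted p = 0.419), with ACLY at 264.2 ± 67.0 and 285.3 ± 32.5 and SCD at 116.2 ± 56.5 and 145.8 ± 18.1, and a mean difference of -0.40 in 09 and 0.056 in 10. Camera called this list lower in 3 of 23 alternatives (lowest adjusted p = 0.0124), against an adjusted p = 0.860 with an estimated correlation in the comparison of groups alone.

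Insulin and growth factor signalling had a median of 0.032 (24 genes, adjusted p = 0.792), with a mean difference of 0.032 in 09 and -0.081 in 10. IGF2, the fetal growth factor, stood at 540.8 ± 209.8 FPKM with norepinephrine and 345.6 ± 111.4 in controls (log2 0.61, SE 0.32, limma adjusted p = 0.698) and differed by 0.14 with the prefix in the model. IGFBP7 stood at 383.4 ± 248.0 and 290.0 ± 53.9, and IRS2 at 5.90 ± 2.77 and 6.48 ± 1.59. With the prefix, FGFR1, a receptor named after its values were seen, was lower adjusted over the list alone (log2 -0.71, limma adjusted p = 0.0488).

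Antigen presentation and interferon response genes were lower as a list (median -0.22, 21 genes, adjusted p = 0.0307; 0.807 with an estimated correlation), with 0 members past the test over all genes and 0 adjusted over the list alone. The mean difference was 0.13 in 09 and -0.75 in 10, and the call was lost with gestational age as a covariate, where the median was -0.25 (adjusted p = 0.585). It was also lost without control 1 (adjusted p = 0.130), control 3 (0.380), norepinephrine 2 (0.395) or norepinephrine 4 (0.111). TAPBP stood at 208.6 ± 14.9 and 239.2 ± 51.4. B2M stood at 4546 ± 1011 and 4646 ± 1814, with a log2 difference of 0.010 that turned negative with equal library totals.

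Among markers of other cells that an islet preparation can hold, acinar transcripts differed most in the comparison of groups alone. All 11 tested acinar genes had higher means with norepinephrine, with a median of 1.04 (adjusted p = 4.59e-05; 0.801 with an estimated correlation). Over all genes 0 passed, and 2 were higher adjusted over the list alone: CPB1, carboxypeptidase B (chromosome 1, 237392618 to 237431369), rose from 21.7 ± 11.5 to 95.0 ± 42.0 FPKM and CELA1, an elastase, from 6.89 ± 2.66 to 15.01 ± 4.20 (limma adjusted p over the list alone 0.00351 and 0.0258). CPA1 stood at 210.5 ± 186.7 and 63.0 ± 12.2 and did not pass. The mean difference was 1.23 in 09 and -0.37 in 10, and with the prefix in the model the list was not called (median 0.52, adjusted p = 0.121), with CPB1 alone higher over the list (adjusted p = 0.0277).

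Duct markers had a median of 0.088 and a mean of 0.40 (11 genes, adjusted p = 0.202), with KRT8 at 1058 ± 230.0 and 1175 ± 78.9 FPKM and EPCAM at 526.5 ± 88.8 and 535.8 ± 66.9, and a mean difference of 0.34 in 09 and 0.029 in 10. Endothelial markers had a median of -0.22 (12 genes, adjusted p = 0.0914) and of -0.47 with the prefix in the model (adjusted p = 0.00862; adjusted p = 0.638 with an estimated correlation), with PLVAP at 89.7 ± 47.9 and 88.1 ± 15.9 and CDH5 at 38.2 ± 20.2 and 47.9 ± 9.64, and a mean difference of -0.25 in 09 and -0.54 in 10. Mesenchymal and stellate cell markers had a median of -0.062 and a mean of 0.029 (19 genes, adjusted p = 0.969), with VIM at 1484 ± 395.9 and 1815 ± 431.7 and SPARC at 520.8 ± 346.3 and 478.0 ± 104.7. The mean difference was 0.39 in 09 and -0.76 in 10, and VIM was lower adjusted over the list alone with the prefix (log2 -0.63, limma adjusted p = 0.0411). Leukocyte markers had a median of 0.018 (15 genes, adjusted p = 0.969), with CD14 at 79.4 ± 26.8 and 69.8 ± 20.1 and LAPTM5 at 57.0 ± 35.2 and 45.4 ± 11.6, and a mean difference of 0.15 in 09 and -0.44 in 10. Neural and Schwann cell markers had a median of -0.045 (7 genes, adjusted p = 0.601), with NCAM1 at 73.4 ± 17.6 and 74.4 ± 8.82 and NEFM at 40.3 ± 10.7 and 56.4 ± 5.68, and a mean difference of 0.028 in 09 and -0.19 in 10. Of the erythroid markers 0 were tested.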

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

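The tests of the 3 patterns and of the splits were chosen only after the results were seen, except for the 09 against 10 gene count with fetal sex and the acinar mean with the prefix, while the settings with a higher filter and with the prefix as a covariate were planned.

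A value was singled out where 1 of the 4 animals of a group lay far from the other 3 by Dixon's test at its 95% critical value. Chance singles out about 1 in 20 groups, or 10.4 of the 208 groups checked, and 28 were found, 14 of them in control 2. Control 2 is the only control numbered 09 and the only female control. Its summed FPKM was 1112624, against 768021 to 796149 in the other controls, and its gestational age was 139 days against 140. Control 2 was also highest for the mean of the glycolysis and hypoxia genes (5.96 against 5.15 to 5.25) and for NNAT (68.2 FPKM), CHGA (6212), SCG5 (4972), NAPA (238.7), GNAS (2696), PRKAR1A (688.9), COX5B (1239), IER3 (255.2), RPL19 (8987), EPCAM (635.3) and VIM (2457).

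Among the other controls, control 1 was highest for the mean of the cell-cycle genes (3.06 against 2.77 to 2.80), GLP1R (10.4 FPKM against 1.42 to 2.82) and CPB1 (39.0). Control 4 was lowest for PDX1 (211.2 FPKM against 267.8 to 279.0) and highest for KRT8 (1292). In the norepinephrine group, animal 1 was highest for the mean of the adrenergic genes (4.77 against 4.62 to 4.65). Animal 2, the only one numbered 10, was lowest for RPL19 (4231 FPKM). Animal 3 was highest for MGAT5B (40.4) and lowest for GPX3 (890.2). Animal 4 was highest for ADRA1B (2.90), HIPK2 (31.7), PCNA (107.9) and TXN (1518), and lowest for HADHB (114.0).

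The first pattern weighed was the 2187 genes that differed between animals numbered 09 and 10. After median-of-ratios scaling 2095 genes passed, but its factors ran only from 0.973 to 1.05, and with equal totals 4346 passed, 1038 of them among the 2187 with the same sign, so scaling between libraries as a source of these differences stays open. The 09 against 10 difference in controls correlated across genes with that in norepinephrine animals (r = 0.38, highest other choice of animals 0.231), which argues against an uneven spread of norepinephrine as the source. With fetal sex in the model 24 genes passed, through wider errors (median SE 0.18 against 0.14), so this count leaves sex open. The median size of the differences stayed at 0.64 against 0.67. These genes were picked for a steady difference between the number groups, and animals numbered 09 include both sexes. A gene that differed by sex alone would seldom be picked, so this size was largely set in advance and decides nothing about sex. Among males, norepinephrine 1 and 4, numbered 09, had summed FPKM of 981583 and 1075998. They lay at 14.9 and 39.3 on the first principal component. Males numbered 10 had at most 796149 and lay at -19.5 or below. These values argue against sex as the only source of the parting of libraries. A part played by sex in single genes stays open. Fetal weight was 2.8 to 3.6 kg in animals numbered 09 and 3.7 to 5 kg in those numbered 10. Gestational age was 137 to 139 days in 09 and 139 to 140 days in 10. Depth relative to control 1, where known, was 1.01 to 1.17 in animals numbered 10 and 0.650 and 0.726 in those numbered 09. Depth, fetal weight, gestational age, collection year, sequencing batch and the animals themselves were not tested as sources and stay open.

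The second pattern was the lower cell-cycle and mitosis transcripts. Members with a mean FPKM of at least 5 had a median of -0.43 (14 genes), which argues against low values as the source. With the number prefix in the model the mean difference was -0.46 (SE 0.16), against -0.48 (SE 0.13) without it. It was -0.42 within animals numbered 09 and -0.50 within those numbered 10. Between the number groups the list was not called (median -0.054, camera adjusted p = 0.583 with the preset correlation). These values argue against the number group as the whole source. A smaller part cannot be excluded, since each number group holds a lone animal of a treatment group. Of the endothelial, mesenchymal and leukocyte markers, the endothelial mean was lowest with the prefix, at -0.39 (SE 0.25). Mesenchymal markers differed by -0.18 (SE 0.58) and leukocyte markers by -0.14 (SE 0.18). Without the prefix these differences were -0.19, 0.029 and 0.026, in the same order. With errors this wide, fewer dividing cells of a non-islet type cannot be told apart from less division in islet cells.

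The third pattern was the higher acinar transcripts. In animals numbered 09, 10 of 11 acinar markers were higher in the norepinephrine animals, against 1 control, and more exocrine tissue there and a difference of that control cannot be told apart. In animals numbered 10, 2 of 11 were higher, CPB1 and CELA1, in the 1 norepinephrine animal. Its acinar mean was 2.93, against 3.23 to 3.39 in the controls numbered 10. The pattern was thus absent in that animal, with no rise for more exocrine tissue to explain. A single animal does not show whether others numbered 10 would differ. With the prefix in the model the acinar mean differed by 0.43 (SE 0.50), against 1.09 (SE 0.61) without it, which cannot be told apart from no difference.

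For genes past the adjusted threshold, 35 of 35 splits gave as many as the real one (0, highest other 2352, the 09 against 10 split), as any split must against a count of 0, so this count does not bear on chance. For genes at an unadjusted p under 0.05, 5 of 35 gave as many (real 975, highest other 4537, again 09 against 10, and 1416 among the rest), a number that chance splits also reach. With the prefix in the model, 1 of the 16 arrangements within number groups gave as many genes at an unadjusted p under 0.05, the real one (1552, highest other 1073), and 16 arrangements are too few for a share under 0.05. For the mean cell-cycle difference, 1 of the 35 splits gave as large a mean, the real one (0.48, highest other 0.40). This repeats the exact permutation test of this list (p = 0.0286) and is no separate check. That test did not pass over the 28 lists (adjusted p = 0.600). Within number groups 2 of the 16 arrangements gave as large a mean (real 0.46, highest other 0.47). There another arrangement, of opposite sign, gave a larger mean than the real one. Even a real value above all others could not reach a share under 0.05 with 16 arrangements.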

How the results depend on the processing

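The settings tried within each number group, and the prefix joined with median-of-ratios scaling, were chosen only after the results were seen. Across 23 alternatives, the cell-cycle and mitosis list stayed lower and was called in 22, the unfolded protein response in 21, islet hormones and acinar markers in 18, antigen presentation and interferon response in 16, oxidative phosphorylation in 14 (12 in the main direction) and ribosomal proteins in 12 (10 in the main direction). Every one of these list calls used the preset correlation, so the tally does not test that choice. For acinar markers, the alternative with their own mean as a covariate had its outcome fixed in advance and tests nothing. The alternative with an estimated correlation called 0 lists. Of 86 named genes tested, 44 kept their sign throughout and 9 turned sign with a scaling. Only NNAT passed anywhere. The median shift over all genes was 0.017, 0.0049 after median-of-ratios scaling and -0.12 with equal totals. INS and PPY were not listed, so that last setting left out only GCG and SST and acted as total scaling. What depth limits was not tested, since the table holds no counts, and a lone animal in a fit is assumed to vary like the others. For the values that follow the cause was not tested, except that a higher filter tests fewer genes and a fit within 1 number group uses fewer animals.

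With the prefix as a covariate, 1 gene changed, NNAT (1 higher), and 1552 genes had an unadjusted p under 0.05. List medians were 0.44 for alpha-cell markers, -0.47 for endothelial markers, -0.25 for glycolysis and -0.19 for antioxidant defence, all 4 now called, 0.52 for acinar markers, no longer called, and -0.090 for oxidative phosphorylation and -0.17 for ribosomal proteins, which reversed, as glycolysis did. With median-of-ratios scaling as well, 1 gene changed (1 higher), 1525 had an unadjusted p under 0.05, and medians were -0.064 for oxidative phosphorylation, -0.22 for glycolysis, -0.16 for antioxidant defence, -0.14 for ribosomal proteins, 0.55 for acinar and -0.45 for endothelial markers.

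With the acinar mean as a covariate, medians were 0.20 for prohormone and granule genes, 0.73 for alpha-cell markers, -0.038 for oxidative phosphorylation, -0.20 for glycolysis, -0.12 for ribosomal proteins, -0.057 for acinar and -0.32 for endothelial markers, and -0.40 for cell cycle, still called. With gestational age, they were 0.50 for islet hormones, 0.23 for beta-cell transcription factors, 0.16 for exocytosis, -0.20 for DNA replication, -0.29 for oxidative phosphorylation, -0.31 for glycolysis, -0.28 for antioxidant defence, -0.23 for immediate-early genes, -0.25 for antigen presentation and interferon response, -0.31 for ribosomal proteins, -0.78 for endothelial and -1.04 for mesenchymal markers. Camera with the preset correlation called 12 lists with this covariate. Only 3 of the 7 main calls were kept in their direction, and 8 calls were new.

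With equal totals, 1 gene changed, NNAT (1 higher), and medians were 0.28 for alpha-cell, -0.037 for duct and -0.36 for endothelial markers. With no filter the ribosomal median was 0.26 and no longer called, and with a mean FPKM of at least 5, 2 cell-cycle members were lower adjusted over the list alone. With an estimated correlation the medians stayed and no list was called: 0.87 for islet hormones (adjusted p = 0.579), -0.56 for cell cycle (adjusted p = 0.579), 0.18 for oxidative phosphorylation (adjusted p = 0.807), 0.42 for the unfolded protein response (adjusted p = 0.801), -0.22 for antigen presentation and interferon response (adjusted p = 0.807), 0.27 for ribosomal proteins (adjusted p = 0.807) and 1.04 for acinar markers (adjusted p = 0.801).

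In animals numbered 09 alone, norepinephrine is set against 1 control, control 2, which is female, while norepinephrine 1 and 4 are male. Treatment, sex and that single control therefore cannot be told apart there. Xist_exon4 differed by -7.71 in this fit. Medians were 0.90 for islet hormones, -0.24 for oxidative phosphorylation, -0.33 for glycolysis, -0.36 for antioxidant defence, 0.0061 for the unfolded protein response, 0.087 for antigen presentation and interferon response, -0.45 for cholesterol synthesis and -0.22 for ribosomal proteins. In animals numbered 10 alone, 15 genes changed (12 higher, 3 lower), 6 of them small nucleolar RNAs, and 1 cell-cycle member was lower adjusted over the list alone. Medians were 0.31 for prohormone and granule genes, 0.85 for alpha-cell markers, 0.22 for exocytosis, 0.052 for oxidative phosphorylation, -0.28 for immediate-early genes, -0.17 for ribosomal proteins, -0.80 for acinar, -0.54 for endothelial, -0.77 for mesenchymal and -0.49 for leukocyte markers.

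With the replicate number as a replicate block, 0 genes changed, 646 had an unadjusted p under 0.05, 6 cell-cycle members were lower adjusted over the list alone, and endothelial markers (median -0.22) were called (adjusted p = 0.0464). It changed no other call. Animals of the same number correlated at -0.156, -0.381, -0.034 and 0.093, and only those numbered 4 correlated best with each other, so the numbers did not pair animals.

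Leaving out 1 animal at a time, 0 to 2 genes changed (0 to 1 higher, 0 to 1 lower), 588 to 2185 had an unadjusted p under 0.05, and 6 to 14 cell-cycle members were lower adjusted over the list alone. Genes that passed were TTC28-AS1_3 and an unnamed gene without norepinephrine 1, and a U1 gene without norepinephrine 3. List medians ran from -0.57 to -0.45 for cell cycle, 0.68 to 1.19 for islet hormones, 0.15 to 0.65 for alpha-cell markers, -0.096 to 0.030 for DNA replication, 0.088 to 0.33 for oxidative phosphorylation, -0.28 to -0.15 for antigen presentation and interferon response, -0.23 to 0.0084 for cholesterol synthesis, 0.17 to 0.49 for ribosomal proteins, -0.030 to 0.31 for duct, -0.38 to -0.055 for endothelial and -0.44 to 0.23 for mesenchymal markers. The weight difference ran from -0.808 to -1.275 kg and the age difference from -1.08 to -1.75 days.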

Other observations

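All genes in this part except RGS2 were chosen only after their values were seen, and none passed limma with adjustment in the comparison of groups alone. OXT, which encodes oxytocin (chromosome 13, 51437893 to 51438654), had the lowest p of all 13252 genes. It stood at 28.9 ± 14.8 FPKM with norepinephrine and 2.97 ± 1.39 in controls (log2 2.87, SE 0.37, limma adjusted p = 0.210), and differed by 2.59 in animals numbered 09 and 2.67 in those numbered 10. OXT shares a near-identical exon with AVP, the vasopressin gene, so its value is uncertain. DBNDD1 stood at 69.5 ± 43.7 and 10.4 ± 2.06 FPKM, and C21orf62 at 4.78 ± 1.83 and 15.1 ± 0.77. EBF4, a transcription factor, stood at 9.95 ± 1.59 and 20.9 ± 2.70, and MGAT5B, a glycosyltransferase, at 34.8 ± 3.76 and 56.0 ± 6.83. The kinase HIPK2 stood at 22.9 ± 5.88 and 10.5 ± 1.61, and TRIM24 at 22.0 ± 0.428 and 13.6 ± 1.33.

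With the number prefix in the model, some differences were larger and 1 was smaller, and none of these genes passed over all genes. SLC2A3, the glucose transporter GLUT3, stood at 36.3 ± 11.5 FPKM with norepinephrine and 60.9 ± 9.35 in controls, and differed by -0.78 without and -1.11 with the prefix. BAX, which promotes apoptosis, stood at 248.3 ± 43.8 and 324.7 ± 63.9 and differed by -0.39 and -0.64. RGS2 differed by -0.28 and -0.57. SEC11C, a subunit of the signal peptidase, stood at 203.9 ± 24.7 and 120.2 ± 20.9 and differed by 0.77 without and 0.63 with the prefix.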
